A study of Mus musculus with 80 samples.

How the data were processed

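Lung RNA of 40 C57BL/6 mice, 20 of them male, was measured on 80 radioactive cDNA arrays, 2 per mouse, with the 17K mouse clone set divided over table A and table B. Per the labels' protocols, the mice had regular feed without restriction, tissue was broken up with glass beads, total RNA was extracted with an RNeasy kit, and cDNA was labelled with 33P-dCTP. The values as deposited by the authors are z scores: each array has a mean of 0 and an SD of 1 over its 8448 spots, with no missing values. Array medians ran from -0.1 to -0.01 on table A and from -0.11 to 0.02 on table B. The scale under the z score, the log base if there was one, the background correction and the spot filters are not given in the sources used here. Effects are therefore in z units and no fold is given. No background measure was used here, so the number of arrays and the spread between mice set the stated precision.

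Age, sex and age group came from the labels, with 5 mice in each of 8 groups. The description of 1 male of 714 days names another mouse, and that male was left out in an alternative. Of the 16896 probes, 9663 had 1 gene symbol, 436 had several and 6797 had none in the platform annotation. Gene numbers of 9641 probes matched the RefSeq gene table of assembly GRCm38.p6, which was used for names only. Spots with several symbols were not named.

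Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), fitted separately in each table, with Benjamini-Hochberg adjustment over the 16896 probes together and a threshold of 0.05. Age slopes, per 100 days with sex as a term, were fitted over all 40 mice and over the 30 mice of 169 days or older. Contrasts of 8 group means gave the steps from 17 to 44 days to 169 to 194 days, from there to 704 to 743 days, and male less female. An interaction term tested whether slopes differed by sex. The 10 youngest mice were divided at the gap between 21 and 33 days, with sex as a term. Of 35 gene lists, 27 had at least 5 measured genes and were tested with cameraPR at a preset inter-gene correlation of 0.01, with 1 probe per gene, the one of highest mean. A listed gene counted as measured if a spot had its symbol and no other. Members were also counted with p adjusted over the list alone. The groups, tests, lists, alternative settings and the rule for named genes were fixed before the data were examined. That rule took up to 10 genes per direction with the smallest p past the threshold, the same sign in both sexes and a symbol that is not a clone or hypothetical-gene name, or 5 per direction within the youngest mice and for the interaction. It added up to 4 members with the smallest p of each list described, and the sex chromosome genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty where measured. Which lists to describe was chosen after their tests were seen.

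The alternatives set then were quantile normalization, leaving out the dimmest 33.3% of probes, eBayes with trend and robust settings, array weights, the number in each mouse's title as a covariate or in runs as a block, log2 of age, other sets of mice, and each mouse left out in turn. For the lists, an estimated correlation and the mean of all probes of a gene were also tried. After the data were seen, spot position, a division of the mice by title number and the 2 females of 704 to 743 days with the lowest correlation to their group on table A were added. Spots were laid out by their number as 16 blocks of 24 lines and 22 columns, a layout read from the data: residuals of spots 22 apart correlated at 0.5 on table A and 0.546 on table B, and spots 528 apart at 0.451 and 0.478. The correction subtracted, for each array, the median deviation of the spots of 1 block and column. The correlations are across spots, which are not independent replicates. Residuals of table B also divided at title number 46: the first component held 30.1% of the residual variance, and 0.898 of it lay between the 27 earlier and the 13 later mice. On table A the second component held 10.8%, and 0.409 of it lay at the same division. The first component of table A held 18%, with 0.033 of it at its best change point, also title number 46. The labels do not say that this number marks a batch.

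All fits were tested on simulated independent normal values with 200 changed probes among 16896. For the slope over 40 mice, 62.7% of probes changed by 0.05 per 100 days were recovered, and 97.0% of those changed by 0.1. For the oldest against the 6-month mice, 34.3% were recovered at 0.25 z and 88.1% at 0.5 z. Within the youngest mice 35.8% were recovered at 0.5 z and 90.9% at 1 z. The simulated values lack the correlation between spots seen in the arrays. The recovered shares also hold for 200 changed probes. Where few probes are called, as the 3 over all 40 mice, the adjustment asks for a smaller p, so these shares overstate recovery there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.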

Results

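Transcript levels in the lung were measured in 40 mice of both sexes, 10 in each of 4 age groups: 17 to 44 days, 169 to 194 days, 476 to 499 days and 704 to 743 days. Each mouse gave 1 array per table. Mean correlations of an array with the others of its group ran from 0.869 to 0.962 on table A and from 0.917 to 0.969 on table B. The stated aim was to compare mice by age and sex. All levels are z scores within an array, so a change is relative to the other spots of that array.

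Across all 40 mice, Sparc, a matricellular glycoprotein that binds collagen, fell with age, and Ighm, the constant region of the immunoglobulin mu heavy chain, rose. In assembly GRCm38.p6 Sparc (gene number 20692) lies on chromosome 11 from 55394159 to 55420080, and Ighm (gene number 16019) on chromosome 12 from 113418826 to 113422730. The brighter Sparc spot (6518) fell by 0.0984 z per 100 days (SE 0.0136, limma adjusted p = 0.000109). Its mean was 1.545 ± 0.256 (SD, n = 10) at 17 to 44 days, 1.104 ± 0.234 at 169 to 194 days, 1.018 ± 0.176 at 476 to 499 days and 0.763 ± 0.199 at 704 to 743 days. All 10 of the oldest mice lay below the lowest of the youngest. A Sparc spot on the other table (14923) had a slope of -0.0404 (SE 0.0074, adjusted p = 0.0129). All 4 Sparc spots had negative slopes, and 2 passed the threshold. The other 2 had slopes of -0.0108 (SE 0.0106, adjusted p = 0.739) and -0.0167 (SE 0.0105, adjusted p = 0.537). Ighm (spot 1606) rose by 0.203 z per 100 days (SE 0.0304, adjusted p = 0.000325), from -0.056 ± 0.122 in the youngest group to 1.306 ± 0.87 in the oldest.

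These 3 spots were the only ones of 16896 past the threshold, 1 upward and 2 downward, while 2324 had an unadjusted p under 0.05. In all, 303 had an adjusted p under 0.06, and leaving out single mice gave between 3 and 631 calls. It was 1188 with log2 of age and 20 after correction for spot position. Among the 27 mice with earlier title numbers the slope of Sparc spot 6518 was -0.0998 (adjusted p = 0.059) and that of Ighm 0.2265 (adjusted p = 0.00567). Among the 13 later ones they were -0.0902 and 0.168, and neither passed (adjusted p = 0.9993).

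**Figure D1:**
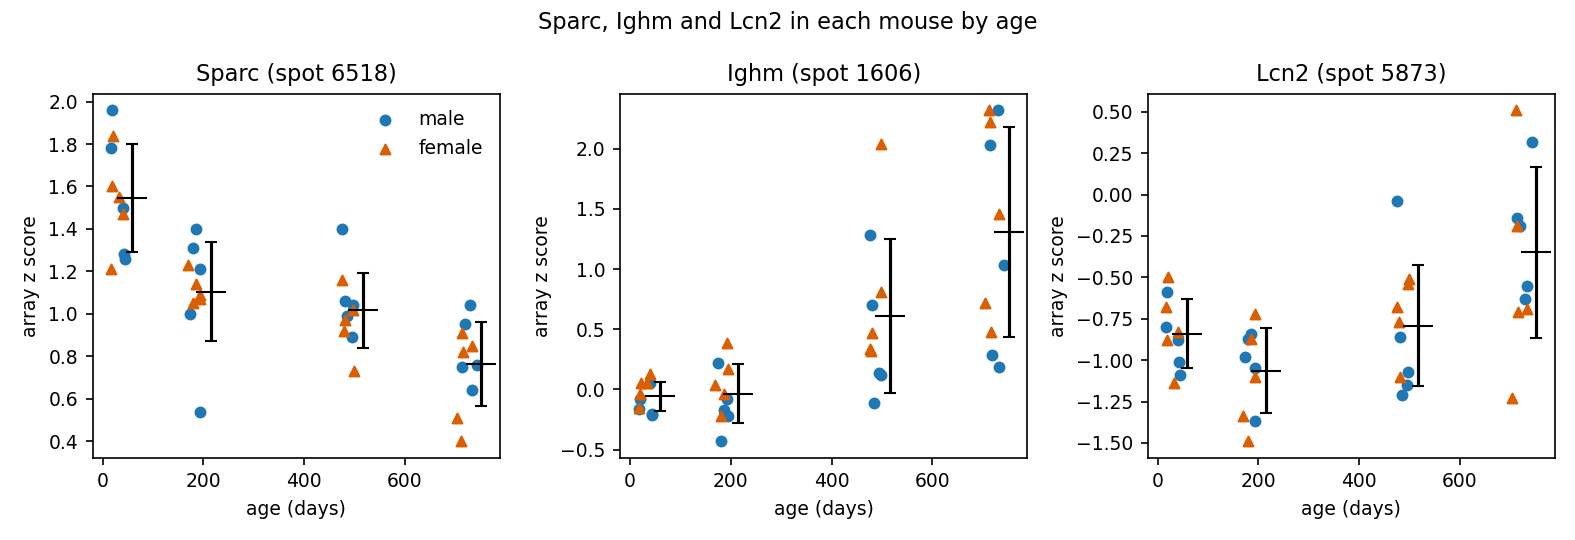
Array z score (vertical axis) against age in days (horizontal axis) for Sparc, Ighm and Lcn2 in each of 40 mice, circles for males and triangles for females; black bars, drawn to the right of each age group, are its mean and SD (n = 10). Sparc means go from 1.545 to 0.763 between the youngest and the oldest group and Ighm means from -0.056 to 1.306; the Lcn2 slope did not pass over all probes (adjusted p = 0.0551).

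Of the lists, only that of extracellular matrix genes was past the threshold with age, shifted downward at a preset correlation (cameraPR adjusted p = 0.00442), and it was not past it with an estimated correlation (adjusted p = 0.322). Of 44 measured members, 14 fell and none rose with p adjusted over the list alone, 1 fell over all probes (Sparc), and 30 did not pass. Besides Sparc, the smallest p belonged to Emilin1, an elastic fibre glycoprotein, with -0.0571 z per 100 days (SE 0.0153), the small proteoglycan Bgn with -0.023 (SE 0.0063) and Sparcl1 with -0.0518 (SE 0.0154). The list was not past the threshold after correction for spot position either (adjusted p = 0.167). Among the earlier title numbers alone its adjusted p was 0.0254, and among the later ones 0.66. That correction took the slope of Emilin1 to -0.0072 (SE 0.0048) and that of Sparcl1 to -0.0011 (SE 0.0046), while Col1a1 stood at -0.0302 (SE 0.0089) against -0.0304 before and Mfap4, a microfibril protein, at -0.0334 (SE 0.0112) against -0.0289. Tnc, which had not passed before (0.0078, SE 0.0078), rose over the list alone after it (0.0381, SE 0.0128). Col1a1, Mfap4 and Tnc were named here after their values were seen.

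**Figure D2:**
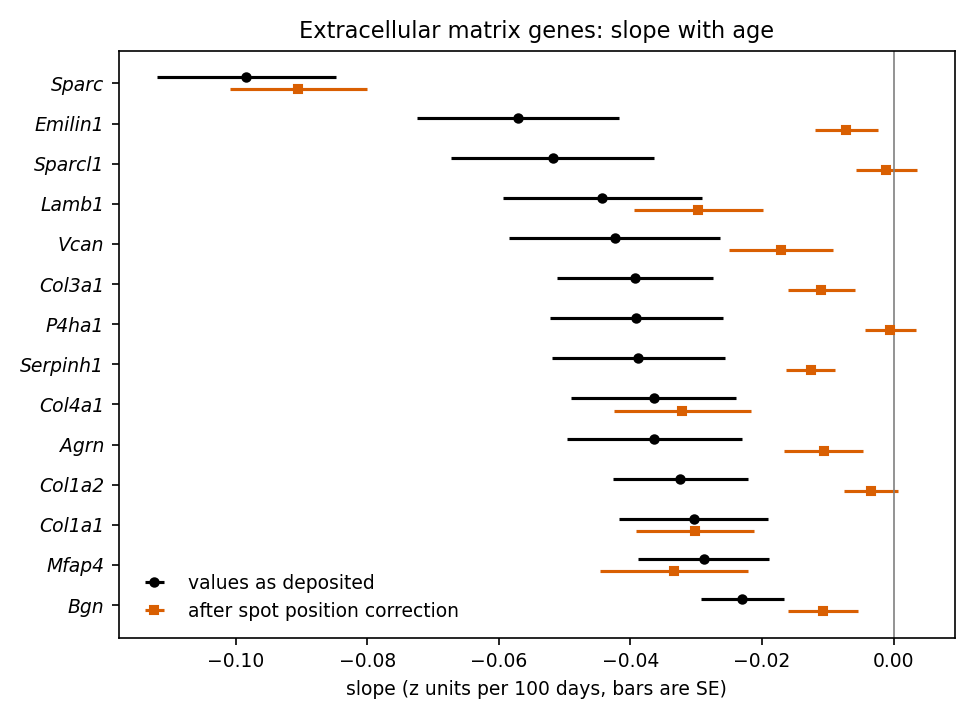
Slope with age in z units per 100 days (horizontal axis, bars are SE, 40 mice) of the 14 extracellular matrix genes that fell with p adjusted over the list alone (vertical axis), from the values as deposited (black circles) and after correction for spot position (orange squares). After the correction 6 of the 14 still passed over the list alone and 9 had less than 0.5 of their slope, while Tnc, not drawn, rose over the list alone. Col3a1 is drawn from 1 of its 4 spots (-0.0393 as deposited), and its other spots had slopes of 0.008, -0.0038 and -0.0045.

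In other lists single members passed over the list alone, but no other list passed the threshold. Among 15 erythroid and blood genes, 6 fell over the list alone, led by the alpha globin genes Hba-a1 (-0.0733, SE 0.0187) and Hba-a2 (-0.1165, SE 0.0328), with Fech, the last enzyme of haem synthesis, and the embryonic globin Hba-x (list adjusted p = 0.338; 0.874 with an estimated correlation). All 12 Hba-a1 spots and all 4 Hba-a2 spots had negative slopes, with adjusted p between 0.0537 and 0.057. Several Hba-a1 spots share a spot column on table B, where residuals of spots 22 apart correlated at 0.546, so the spots are not independent. The slope of Fech turned to 0.0014 with the correction by spot column. Of 41 chaperones, 6 fell over the list alone, with slopes of -0.0945 for Hspa4, -0.032 for Dnajb1, -0.0444 for Cct2 and -0.0426 for Hspa9 (list adjusted p = 0.947); Hspa9 turned to 0.0069 after correction for spot position by block and column. Of 59 oxidative phosphorylation genes, Atp5b and Atp5g1, both of ATP synthase, fell over the list alone (-0.0629 and -0.0533). Ndufs7 of complex I rose over it (0.0223), while Cox10 had -0.0506 and did not pass. The list's cameraPR adjusted p was 0.263. Hspa4 and Dnajb1 lie in spot column 8 of table A, Atp5g1 in column 8 of table B, and Atp5b and Cox10 in its column 9. In those columns 81 of 81, 131 of 135 and 251 of 254 calls within the youngest mice, given below, were falls. Cct2 lies in column 6 of table B (24 of 45 fell) and Ndufs7 in column 3 (7 of 7 rose).

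Among 11 genes of alveolar type II cells, Lcn2, an iron-siderophore binding protein that is also on the list of neutrophil genes, rose over the list alone (0.0777, SE 0.0216), and the surfactant lipid enzyme Lpcat1 fell (-0.0386, SE 0.0108). Slc34a2 had -0.0297 and S100g 0.0212, and neither passed (list adjusted p = 0.947). The other neutrophil genes Ltf, Csf3r and S100a9 had slopes of 0.0215, 0.0109 and -0.0075. Ces1d, an esterase on the list of club and ciliated cells, rose over that list alone (0.0367, SE 0.0106); Cbr2, Tekt2 and Dynlrb2 had 0.0259, -0.0371 and 0.0092. The growth inhibitor Cdkn1c rose among 14 imprinted genes (0.0309, SE 0.0082), with Plagl1 at -0.043, H19 at 0.0247 and Slc38a4 at 0.0165. The 7 H19 spots had slopes from 0.0033 to 0.0247, and none passed over all probes. Ifi27 rose among 14 interferon response genes (0.0214, SE 0.0069), with Irf9, Lgals3bp and Gbp2 at 0.0173, 0.016 and 0.0116. Cd74, the invariant chain of MHC class II, rose over its 3 genes alone (0.0302, SE 0.012), with H2-Eb1 at 0.0149 and H2-DMa at -0.0032. Sdc1, the other measured gene of B and plasma cells beside Ighm, had 0.0026 (SE 0.0117).

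Among the 30 adult mice, limma called 0 probes, with 438 at an unadjusted p under 0.05 and a smallest adjusted p of 0.156. Sparc had a slope of -0.0624 (SE 0.017) and was the 1 matrix gene that fell over its list alone, with P4ha1, Bgn and Mfap4 at -0.0319, -0.016 and -0.0222. Lcn2 rose over the list of alveolar type II cells alone (0.131, SE 0.0308), with Fabp5, Muc1 and Sftpd at 0.017, 0.0242 and 0.019. Both lists had an adjusted p of 0.0937. Ighm means in these mice were -0.034 ± 0.245 (SD, n = 10) at 169 to 194 days, 0.611 ± 0.641 at 476 to 499 days and 1.306 ± 0.87 at 704 to 743 days. Of the 2 measured genes of B and plasma cells, 1 rose over the list alone.

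From 17 to 44 days to 169 to 194 days, limma called 0 probes over all, with 1004 at an unadjusted p under 0.05 and a smallest adjusted p of 0.819. Over the lists alone, Sparc fell by 0.441 z (SE 0.0991), and so did 3 genes of alveolar type II cells: the mucin Muc1 by 0.279 (SE 0.0915), the phosphate transporter Slc34a2 by 0.251 (SE 0.0851) and Lpcat1 by 0.221 (SE 0.0823). Cd74 and H2-Eb1 rose over the 3 MHC class II genes alone, with 0.209 (SE 0.0794) and 0.239 (SE 0.0928), and H2-DMa had -0.032. Members that did not pass were Emilin1 (-0.315), Col3a1 (-0.219), Col1a2 (-0.195), Elovl1 (0.196), Ces1d (0.24), Cbr2 (0.129), Dynlrb2 (0.09), Tekt2 (-0.203), Ifi27 (0.132), Gbp2 (0.098), Ifitm3 (0.105) and Rsad2 (0.287). The blood genes Hba-a1 (-0.351), Hba-a2 (-0.617), Hbb-y (-0.292) and Alas2 (-0.231) did not pass either, and against the 33 to 44 day mice alone Hba-a2 stood at 0.0122, Hbb-y at 0.025 and Alas2 at 0.0263. List adjusted p was 0.069 for the extracellular matrix and 0.0838 for interferon response, alveolar type II, club and ciliated, and blood genes. With an estimated correlation each was 0.438. Sparc stood at -0.4425 among earlier and at -0.455 among later title numbers, but Emilin1, Col3a1 and Col1a2 were positive among the later ones (0.275, 0.215 and 0.168), as was Hba-a2 (0.805).

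From 169 to 194 days to 704 to 743 days, Ighm rose by 1.34 z (SE 0.237, limma adjusted p = 0.0291), the 1 probe called, with 423 at an unadjusted p under 0.05. All 10 of the oldest mice lay above the 6-month mean, and 8 of 10 above the highest 6-month mouse. The difference was 1.42 among earlier and 1.11 among later title numbers. The call held in 33 of 54 settings, with differences from 1.1075 to 1.4627. Those settings include leaving out in turn each mouse of the other age groups, which are not compared here, and none of these fits lost the call. It was lost on leaving out any 1 of 14 of the 20 mice compared (adjusted p from 0.0536 to 0.127), the male of 714 days with conflicting labels among them (1.23, adjusted p = 0.126). It was also lost with trend and robust settings, with only both groups fitted, within earlier or later title numbers alone, and with spot position corrected (1.26, adjusted p = 0.0663). Lcn2 rose over the list of alveolar type II cells alone, by 0.713 z (SE 0.156, adjusted p over all probes 0.321), and 9 of 10 oldest mice lay above the highest 6-month mouse. Fabp5, Muc1 and Lpcat1 had 0.094, 0.139 and -0.096. Sparc had -0.341 (SE 0.0991) and Bgn, Mfap4 and P4ha1 -0.084, -0.131 and -0.177; none of the 44 matrix genes passed over the list alone, and both lists had an adjusted p of 0.0885. Cd74 (-0.001, SE 0.0794), H2-Eb1 (-0.108, SE 0.0928), H2-DMa (-0.002) and Sdc1 (-0.002, SE 0.0913) did not pass.

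Between males and females limma called 0 probes, with 245 at an unadjusted p under 0.05. Xist, the RNA that coats the inactive X chromosome, had a male less female difference of -0.169 z (SE 0.0635, adjusted p = 0.9998 over all probes), Eif2s3y 0.1045 (SE 0.063) and Uty 0.006 (SE 0.0574), the last 2 on the Y chromosome. Kdm6a and Kdm5c had -0.075 and -0.0545. None of these 5 spots passed. The sex chromosome genes were set as a control, so a known difference between the sexes was not called. The 0 calls therefore do not show that the sexes were alike, and these spots cannot check the sex labels. Among immediate early genes, Klf6, Fos, Atf3 and Egr1 had 0.1255, 0.0785, 0.114 and 0.049, and the smallest list adjusted p was 0.416. The slope with age differed by sex for 0 probes in limma, with 339 at an unadjusted p under 0.05.

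Within the youngest mice, 1264 probes differed between 5 mice of 33 to 44 days and 5 of 17 to 21 days, 332 upward and 932 downward. The count rested on single mice: with 1 mouse left out at a time, limma called 0 without male 3 (2300 at an unadjusted p under 0.05) or female 5 (2518), 409 without female 1, 452 without female 3 and 1944 without female 4. Haemoglobin genes were lower in the older mice: Hba-a2 fell by 1.26 z (SE 0.2, limma adjusted p = 0.0105), Hba-a1 by 0.659, Hbb-y by 0.644 and Alas2, the erythroid enzyme of haem synthesis, by 0.527. Of 15 blood genes, 2 rose and 6 fell over the list alone (list adjusted p = 0.187). Of 44 matrix genes 3 rose and 14 fell, led by Agrn (-0.445), Sparcl1 (-0.513), Emilin1 (-0.47) and Col1a1 (-0.422), with a list adjusted p of 0.131. Of 70 genes with ribosomal protein prefixes, which take in the kinase Rps6ka3, 2 rose and 13 fell, led by Rps6 (-0.505), Rpl4 (-0.528), Rps6ka3 (-0.4675) and Rpl24 (-0.3775), with a list adjusted p of 0.28. Over all probes, the smallest p upward belonged to Mbtd1 (1.35, SE 0.25), Mphosph8 (0.592), Bysl (0.4675), Prpf31 (0.49) and Slc27a4 (0.39). Downward they belonged to Kmt5c (-1.23, SE 0.161), Myg1 (-0.932), Pan3 (-0.681), Atg2a (-0.958) and Cox16 (-1.195).

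The calls were not spread evenly over spot columns. On table A, 187 of 199 called probes lay in 3 of the 22 spot columns, and on table B 492 of 1065. Of the genes named above, Kmt5c, Myg1, Atg2a and Cox16 lie in column 8 of table A, Hba-a2 in column 12 and Pan3 in column 21. These are the 3 fullest columns of that table, and every call in them was a fall. On table B, Agrn, Rpl24 and Hba-a1 lie in column 7, and Hbb-y and Col1a1 in column 8. Emilin1 and Rps6ka3 lie in column 9, Rps6 and Rpl4 in column 10 and Sparcl1 in column 12. In that order, falls made up 91 of 101, 131 of 135, 251 of 254, 98 of 103 and 63 of 72 calls there. Alas2 lies in column 16, where 25 of 28 calls rose. After correction by block and column limma called 0, with 2750 at an unadjusted p under 0.05, and Sparcl1 turned to 0.0631. With later title numbers as a block it called 0, with 3086 at an unadjusted p under 0.05, and among the 8 earlier mice alone 0, with 2841. Both later mice were in the older part, so the later mice alone gave no value.

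**Figure D3:**
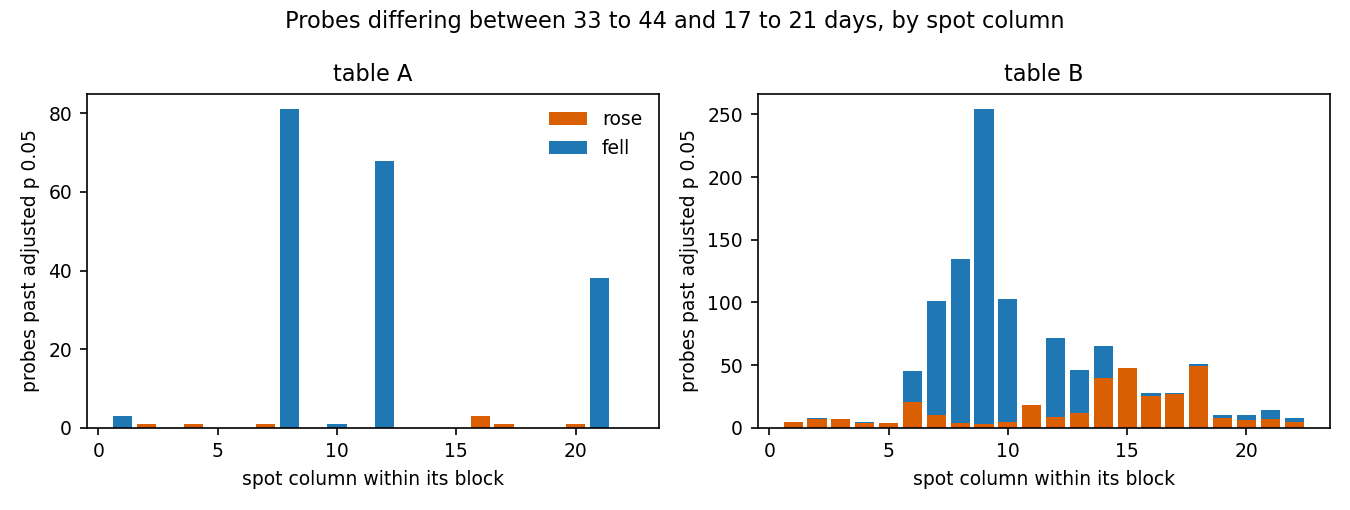
Number of probes past an adjusted p of 0.05 between 33 to 44 and 17 to 21 days (vertical axis, orange rose, blue fell, 10 mice) by spot column within its block (horizontal axis), for table A and table B. On table A 187 of 199 calls lie in 3 columns.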

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

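The tests of spot position, of title number and of lymphoid tissue were chosen after the results were seen; the counts over other splits of the mice were planned.

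Within the youngest mice, 1264 probes differed between 33 to 44 and 17 to 21 days, Hba-a2 and Kmt5c among them. On table A, 94% of the calls (187 of 199) lay in 3 of 22 spot columns that hold 13.6% of the spots, and on table B 46.2% (492 of 1065). Correction by block and column left a median of 0.39 of the effects on table A and 0.346 on table B. It left 0 limma calls, at a smallest adjusted p of 0.054, and 152 probes under 0.06. Correction by column left 507 calls, 401 of them among the 1264. On table B 251 of 254 calls in column 9 fell and 48 of 48 in column 15 rose, while column 14 had 40 rises and 25 falls. Spot position is a candidate explanation for table A. It stays open for table B, where the share fell short of the bound set. Age itself, before and after weaning, stays open too and was not tested. For title number, a shift of the 2 later mice without any noise could reach a t of only 2.25, against at least 3.49 for the calls. Real spots also carry noise, which correlates between spots, so that bound does not exclude title number. Whether such a shift made or added to the calls cannot be told apart from age. The called effects kept a median of 0.808 among the earlier mice alone, but being called favoured a high ratio, so it decides nothing. Leaving out 1 mouse gave 0 calls without male 3 or female 5, 409 without female 1, 452 without female 3 and 1944 without female 4. Of 100 splits 2, the real one included, called as many probes (real 1264, highest other 1504, with 1 mouse exchanged), under 5 in 100, but with 0 calls left without either of 2 mice chance is not firmly excluded; the 46 other splits with both later mice together had a median of 0 and the 53 that parted them called at most 1.

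Across all 40 mice the extracellular matrix list was shifted downward with age at a preset correlation (adjusted p = 0.00442) but not with an estimated correlation (adjusted p = 0.322), and Sparc fell. For Sparc spot 6518, spot position as the whole cause is argued against, since the slope corrected by block and column kept 0.92 of its size and passed (adjusted p = 1.24e-06), while spot 14923 passed after that correction (-0.0391, adjusted p = 0.00285) but not after the one by column (-0.0276, adjusted p = 0.0679). For the list, the test set on the median slope decides neither spot position nor title number. The list's median of -0.0075 (quartiles -0.0311 to 0.0093) lies over members that go both ways. It kept 0.571 after position correction, where the call ended (cameraPR adjusted p = 0.167). Of the 14 genes that fell over the list alone, 9 then had under 0.5 of their slope and 4 over 0.8. What ended the call was not tested. With the later mice as a block the median kept 0.897 and the list still passed (cameraPR adjusted p = 0.0132). At the preset correlation the call thus did not hang on the shift between earlier and later mice alone. Among later title numbers alone the list's cameraPR adjusted p was 0.66. Of 100 splits, 37 put as many lists past the threshold (real 1, highest other 3), so chance cannot be excluded for the list. For the probe count 2 splits, the real one included, called as many (real 3, highest other 8), under 5 in 100. The count itself was unstable, since 303 probes had a limma adjusted p under 0.06 and leaving out 1 mouse gave up to 631 calls. With 8 calls in another split, chance is not firmly excluded there either. A change of matrix expression with age stays open and was not tested further.

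Ighm rose with age. Spot position as the whole cause is argued against by the corrected slope, which kept 0.944 of its size and passed (adjusted p = 0.000685), with a median slope of 0.004 and a highest of 0.0347 among its 23 neighbours, and title number by the oldest less 6-month difference, which kept at least 0.826 in earlier and later mice alike. Of 100 splits 4, the real one included, called as many probes between the oldest and the 6-month mice (real 1, highest other 1), under 5 in 100, but the count of 1 fell to 0 on leaving out any 1 of 14 of the 20 mice and the call held in 33 of 54 settings, so chance is not firmly excluded. Lymphoid tissue or B cells in the sample may be a source: neither Cd74 nor H2-Eb1 was higher in the oldest mice (the higher difference was -0.013 standard errors), but both spots lay above 72.7% and 69.2% of their tables, so a baseline could hide a share, and the bound set on that level was made more cautious after a first run had excluded this source. More antibody-producing cells in the old lung stay open, since of the listed B and plasma cell genes only Ighm and Sdc1 had a spot with 1 symbol.

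For the other comparisons the real count was 0, so all 100 of 100 splits gave as many whatever the mice, and these counts say nothing about chance. The highest count of probes in another split was 1105 for the adult slope, 1112 for the youngest against 6 months, 158 for sex and 241 for age by sex, each in a single split, with 238 and 17 in 2 others for the adult slope. Such splits may reflect a structure of the mice or spots that vary together, and neither was tested. For lists the highest was 2, 2, 4 (oldest against 6 months), 3 (sex) and 3 (within the youngest).

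In 4 places 1 sample lay far from the 4 others of its group. The mean correlation with its own group was 0.896 for male 3 of 169 to 194 days on table A and 0.926 for female 5 of 17 to 44 days on table B. Ighm stood at 2.04 in female 2 of 476 to 499 days, and Atg2a at -0.09 in female 4 of 17 to 44 days. The lowest correlations on table A belonged to females 3 (0.869) and 5 (0.885) of 704 to 743 days, which were left out together in an alternative for that reason; being 2 in 1 group, neither lay alone. The 4 samples are 1 of 8 groups on each table, 1 of 32 for the Sparc, Ighm and Lcn2 spots and 1 of 20 for genes named in the youngest mice, where chance gives about 1 in 20. Over every named spot 35 of 640 groups (5.5%) held such a sample.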

How the results depend on the processing

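Position, division by title number and the 2 outlying females were alternatives added after the data were seen; the others were planned. Of 362 list values 336, and of 1627 named gene values 1353, kept their direction and side of the threshold, and 153 of 194 counts stayed within 1.5 times. Ighm passed over all mice in 55 of 56 settings (slopes per 100 days 0.1681 to 0.2265, log2 of age apart), Sparc spot 6518 in 54 (-0.103 to -0.09), Sparc spot 14923 in 51 (-0.0436 to -0.0276), and Ighm in the oldest against 6 months in 33 of 54 (1.1075 to 1.4627), counting fits that left out a mouse of neither group. The cause was not tested, except that fewer probes or mice were tested where some were left out. Calls over all mice numbered 458 without the dimmest probes, 118 with trend and robust settings, 1313 with array weights, 404 with title runs as block, 1188 with log2 of age, 613 with log2 of age and position correction, 20 after correction by block and column, 1 among earlier and 0 among later title numbers (limma, 323 at an unadjusted p under 0.05). The adult slope had 1 call without the dimmest probes or with title runs as block. The step from the youngest to 6 months had 1 after either correction, which was Sparc. For the oldest against 6 months limma called 0 with trend and robust settings (401 at an unadjusted p under 0.05), without the 714-day male (369), with only both groups (402), after correction by block and column (575) or column (524), and among earlier (519) or later (894) title numbers; it called 2 with title number as covariate, with later numbers as block and without both outlying females. Within the youngest limma called 1 with title runs as block, 507 after correction by column, and 0 after correction by block and column (2750), with later numbers as block (3086) and among earlier numbers (2841); later numbers alone could not be fitted. Lists past the threshold numbered 0 over all mice with an estimated correlation, either correction, log2 of age with correction, or later numbers alone; 1 for the adult slope and the oldest mice without the dimmest probes, with title number as covariate or later numbers as block; and 1 for the youngest against 6 months without the dimmest probes or with array weights. Leaving out single mice gave 3 to 631 calls over all mice: 591 without male 1, 503 without male 5 and 599 without female 5 of 17 to 44 days, 299 without male 1, 631 without male 3, 493 without female 2, 261 without female 3 and 278 without female 5 of 169 to 194 days, 565 without male 2 of 476 to 499 days, and 463 without male 1, 5 without male 3, 407 without male 4 and 6 without female 1 of 704 to 743 days. The adult slope gave 0 to 1, with 1 without male 5 of 704 to 743 days. The oldest against 6 months gave 0 to 2: 0 without males 1, 2, 3 or 4 or females 1, 3, 4 or 5 of 169 to 194 days or males 1, 2 or 4 or females 2, 3 or 4 of 704 to 743 days, and 2 without female 5 of the latter; Ighm then ranged from 1.1965 to 1.4627. Within the youngest it was 0 to 1944: 409 without female 1, 0 without male 3, 452 without female 3, 1944 without female 4 and 0 without female 5. Sex, age by sex and the step from the youngest to 6 months stayed at 0. Lists gave 1 to 1 over all mice, 0 to 1 for the adult slope (1 without male 4 of 169 to 194 or female 5 of 704 to 743 days), 0 to 3 for the youngest against 6 months (2 without female 1 of 17 to 44 days, 3 without males 1 or 3 or female 4 and 1 without female 5 of 169 to 194 days) and 0 to 1 for the oldest (1 without males 1 or 4 of 169 to 194 or male or female 5 of 704 to 743 days). Signs turned among single mice left out for H2-DMa over all mice (-0.0076 to 7e-04) and in the oldest (-0.0485 to 0.0422), Sdc1 (-0.0065 to 0.008, and -0.0748 to 0.0553 in the oldest), Cd74 in the oldest (-0.0535 to 0.0277), Uty by sex (-0.0189 to 0.0317) and the alveolar type II cells list over all mice (adjusted p 0.8624 to 0.9978). Other settings turned the sign of 72 gene values and 13 list values, of which 50 and 7 had an unadjusted p of 0.05 or more in both. Without the dimmest probes these were the alveolar type II cells list (adjusted p = 0.772) for the slope over all mice. With array weights these were H2-DMa 0.0033 for the slope over all mice, and H2-DMa 0.0401 for the step from the youngest to 6 months. With title number as covariate these were H2-DMa 0.0068 for the slope over all mice, and H2-DMa 0.0485, Cd74 0.0019 and Sdc1 0.006 for the oldest against 6 months. With log2 of age these were the alveolar type II cells list (adjusted p = 0.876) for the slope over all mice. After position correction by block and column these were Hspa9 0.0069, S100g -1e-04, Ltf -0.0022, S100a9 0.0019, Dynlrb2 -0.0033, the alveolar type II cells list (adjusted p = 0.871) and the club and ciliated cells list (adjusted p = 0.997) for the slope over all mice, and Sdc1 0.0032 for the oldest against 6 months, and Uty -0.0155 for sex, and Sparcl1 0.0631 and the ribosomal proteins list (adjusted p = 0.948) for the youngest mice. After correction by column these were Fech 0.0014, S100a9 0.0053, Dynlrb2 -0.0012, Sdc1 -3e-04 and the alveolar type II cells list (adjusted p = 0.986) for the slope over all mice, and the ribosomal proteins list (adjusted p = 0.904) for the youngest mice. With later title numbers as block these were H2-DMa 0.0044 for the slope over all mice, and H2-DMa 0.0258 and Sdc1 7e-04 for the oldest against 6 months. Among earlier title numbers alone these were H2-DMa 0.0037 for the slope over all mice, and H2-DMa 0.0067 for the step from the youngest to 6 months, and H2-DMa 0.0021, Cd74 0.0308 and Sdc1 0.0125 for the oldest against 6 months, and Uty -0.0038 for sex. Among later title numbers alone these were Irf9 -6e-04, S100g -0.0015, Csf3r -0.0146, S100a9 0.0058, Tekt2 0, Dynlrb2 -1e-04, Slc38a4 -0.0179, Cd74 -0.0021, H2-Eb1 -0.0148, H2-DMa 0.0077, Sdc1 -0.0122 and the club and ciliated cells list (adjusted p = 0.89) for the slope over all mice, and Emilin1 0.275, Col3a1 0.215, Col1a2 0.168, Elovl1 -0.09, Cbr2 -0.228, Dynlrb2 -0.0425, Ifi27 -0.04, Ifitm3 -0.215, H2-DMa 0.005, Hba-a1 0.393, Hba-a2 0.805, Hbb-y 0.242, Alas2 0.25, the extracellular matrix list (adjusted p = 0.978), the club and ciliated cells list (adjusted p = 0.291), the interferon response list (adjusted p = 0.978) and the erythroid and blood list (adjusted p = 0.291) for the step from the youngest to 6 months, and Lpcat1 0.01 and H2-DMa 0.0375 for the oldest against 6 months, and Atf3 -0.015 for sex. Without both outlying oldest females these were H2-DMa 0.002 and Sdc1 -0.0072 for the slope over all mice, and H2-DMa 0.0273 and Cd74 0.038 for the oldest against 6 months. With log2 of age and position correction these were Sparcl1 8e-04, Hspa9 0.0113, S100g -1e-04, S100a9 0, Dynlrb2 -0.0018 and the alveolar type II cells list (adjusted p = 0.576) for the slope over all mice. With 33 to 44 days as the youngest group these were Cbr2 -0.0068, Tekt2 0.0175, H2-DMa 0.0238, Hba-a2 0.0122, Hbb-y 0.025 and Alas2 0.0263 for the step from the youngest to 6 months. With quantile normalization these were Cd74 1e-04 for the oldest against 6 months, and Uty -0.0045 for sex. Without the 714-day male these were Cd74 0.0153 for the oldest against 6 months. Signal over background was not measured, so what depth limits cannot be given.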

Other observations

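The list tests below were planned, and the choice of which to describe was made after the results were seen. Across all 40 mice 2 of the 4 thymus and immature lymphocyte genes fell with p adjusted over the list alone. In macrophages (3 genes), cardiac and skeletal muscle (4) and oesophagus, trachea and thyroid (2) 0 did by limma. No listed T and NK cell gene had a spot with 1 symbol. List adjusted p was 0.884 for club and ciliated cells, 0.947 for imprinted genes, 0.263 for interferon response, 0.36 for the proteasome and 0.338 for smooth muscle, pericytes and fibroblasts. Of 93 cell cycle genes 1 rose and 3 fell over the list alone (adjusted p = 0.969). The erythroid list had a positive median slope (0.0043) with a negative mean t (-0.763) and a downward test; chaperones (0.0041 and -0.118) differed in the same way, and club and ciliated cells the other way (-0.0007 and 0.412). Within the youngest mice the erythroid median was 0.0325 and its mean t -1.441. Of the 1264 probes called there, 765 had a gene symbol and 499 had none.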
